A study of Mus musculus with 9 samples.

How the data were processed

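RNA was measured in gastrocnemius muscle of mice aged 6, 15 and 21 months, with 3 libraries per age, each from a separate mouse according to the series' design text. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was selected with oligo(dT) beads, and libraries were sequenced from DNA nanoballs. The authors deposited 1 table with an estimated count of reads for each of 17314 genes, given by Entrez ID and symbol, in each of the 9 libraries. The deposited values need not be whole numbers, since between 90.0 and 90.7% of the values in a library were whole within a tolerance of 0.005. The genome build was mm10, per the submitters' processing notes. The aligner, the counter, its annotation and whether it used the strand are not given in the sources used here. Oligo(dT) selection favours polyadenylated RNA and depends on RNA integrity, and estimated counts share reads between similar genes, which makes values of near-identical copies uncertain.

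Columns were matched to samples by the life stage and replicate number in their names and in the titles, and 0 columns belonged to other samples. Entrez IDs were matched to a RefSeq table of the mouse assembly GRCm38.p6, of which mm10 is another name for the chromosomes used, and 17188 of 17314 IDs were found. Coordinates come from that table, 1-based, and the overlap of Thra and Nr1d1 from the exons of a GENCODE annotation of the same assembly.

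Estimated counts were rounded to whole numbers, genes were filtered with filterByExpr (minimum count 10), and libraries were scaled with TMM factors, which ranged from 0.923 to 1.05. This left 13044 genes. The quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) was fitted to all 9 libraries with age as a factor, so that the spread was shared, with 6 residual and 4.24 prior degrees of freedom. Ages were compared pairwise, all 3 together with an F-test, and 15 months with the mean of 6 and 21 months. P-values were adjusted over all tested genes by Benjamini-Hochberg with a threshold of 0.05. Levels are CPM with TMM scaling, given as mean ± SD, and log2 fold changes are given as older minus younger with their SE. For Thra and Thrb an exact permutation test of CPM was added, which cannot go below 0.1 with 3 against 3 mice.

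Gene lists, 35 in all, were fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for naming genes. The 29 lists with at least 5 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The rule took, per comparison, up to 10 genes with the largest rise and 10 with the largest fall among genes past the threshold with non-overlapping groups, a mean of at least 1 CPM in the higher group and a symbol that is not a predicted, Rik, Gm, LOC or pseudogene name, the 5 smallest p-values, list members past the threshold, Thra and Thrb, and as examples the 2 members of a called list with the highest mean. The value of 1 such example is not reported here. Exceptions, chosen after their values were seen, were members past the threshold adjusted over their list alone, Myh7, Myh2, Myh4 and Cd74 as descriptions of single libraries, and a set of 13 endoplasmic reticulum genes including Xbp1, described only among the closing observations. A contrast of the mean of 15 and 21 months with 6 months was also added after the data had been seen and is given only among the closing observations.

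Alternatives fixed in advance were DESeq2 1.42.0, RLE scaling, no filter, a filter of at least 5 CPM in 3 libraries (10170 genes), the replicate number as a block, only the 2 groups compared, sample quality weights (limma voom), an unadjusted threshold for the overlap, and leaving out each library. Total count scaling and leaving out the 3 outlying libraries on the first principal component were added after seeing the data. Total counts per library ranged from 15354396 to 17317856, so low genes carry counting error on top of the spread between mice.

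The procedure was tested on simulated counts, drawn independently for each gene from the real means and library sizes with 200 changed genes. For 21 against 6 months (12944 genes) it recovered 17.9% of genes changed 1.5-fold, 55.2% at 2-fold and 92.4% at 4-fold, with 7 false calls of 117. For 15 against 6 months (12951 genes) it recovered 10.4, 64.2 and 90.9% at the same folds, with 11 false calls of 121. For 21 against 15 months (12959 genes) it recovered 28.4, 82.1 and 97.0%, with 3 false calls of 141. A list shifted by -0.3 in the simulation was called in each comparison (camera adjusted p 8.93e-10, 3.06e-05 and 1.59e-08 in that order), and 0 of the other 28 lists were called. Members of the simulated lists varied independently. In the real data the estimated correlation ran from -0.07 for satellite cell markers to 0.97 for erythrocyte markers. The simulation therefore cannot show how often camera at its preset correlation calls real lists without an effect of age. The shares of genes recovered also apply to independent genes and need not hold for the real libraries.

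Overlap between the comparisons against the same 6-month mice was set beside 20 simulations of unchanged groups, with each gene drawn independently. Pairs of libraries of the same age differed by 10.0 to 70.6 in chi-square per degree of freedom, so none were treated as repeats of the same library. Lists with fewer than 5 measured members were left out of the tests, among them mitochondrially encoded genes, none of which was matched by symbol.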

Results

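Gastrocnemius, the large calf muscle made mostly of fast fibres, was profiled by RNA sequencing in mice aged 6, 15 and 21 months. Each age was represented by 3 mice with 1 library per mouse, and the design text describes them as separate animals. The table of estimated read counts listed 17314 genes, of which 13044 passed the expression filter. Total counts ranged from 15354396 to 17317856 per library. Myh4, the myosin heavy chain of the fastest fibres, took 3.53 to 6.01% of the counts. The biological coefficient of variation between mice of an age was 0.164. The series title names thyroid hormone receptor alpha and skeletal muscle aging, so the comparisons ask which genes differed between ages and how the receptor genes themselves were expressed.

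Slow fibre genes differed widely between mice of the same age. Myh7, the slow myosin heavy chain, stood at 0.438 CPM (counts scaled to library size) in mouse 2 of the 6-month group, at 166 CPM in mouse 1 of the 15-month group and at 156 CPM in mouse 3 of the 21-month group. Myh2, the myosin of fast oxidative fibres, stood at 0.751 CPM in the first of these libraries and at 4395 and 3642 CPM in the others. The first principal component held 35.2% of the variance and set these libraries apart, with coordinates of -48.0 for the 6-month library and 27.6 and 26.7 for the older pair. Because 3 libraries lay far out on this axis, counts and lists were also computed without them, an alternative chosen after seeing the data.

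**Figure D1:**
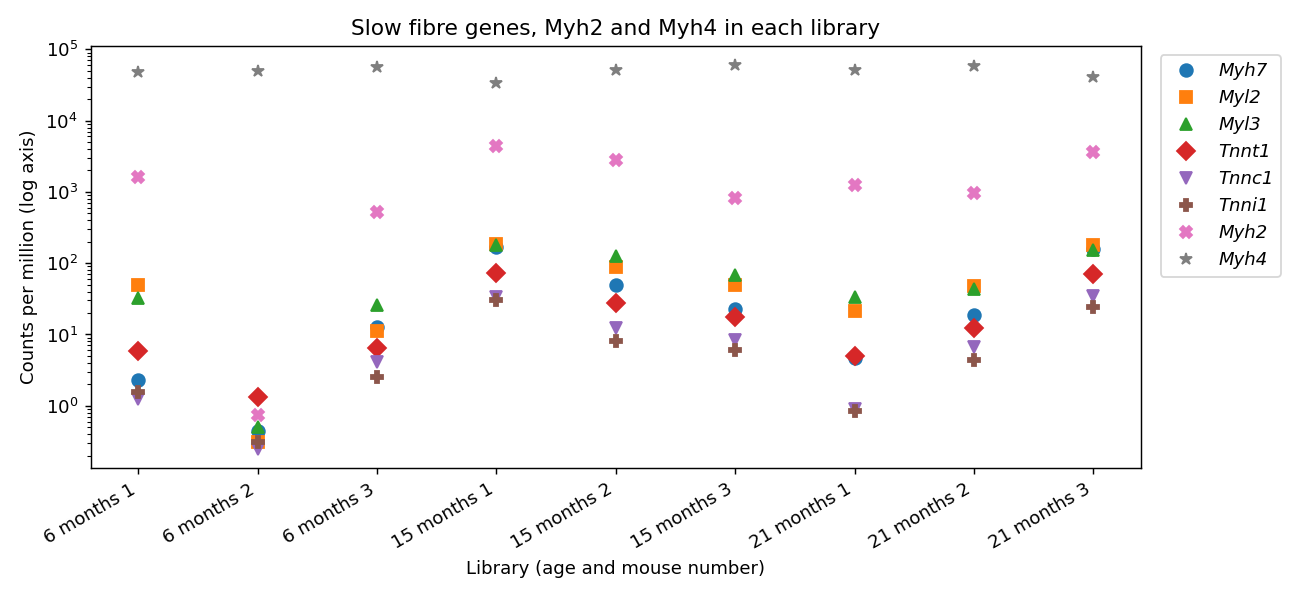
CPM, on a log axis, of 6 slow fibre genes, Myh2 and Myh4 in each of the 9 libraries. Each point is 1 gene in 1 mouse. Myh7 ranged from 0.438 CPM in mouse 2 at 6 months to 166 CPM in mouse 1 at 15 months.

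Thra, which encodes thyroid hormone receptor alpha (Entrez ID 21833, chromosome 11, 98740776 to 98769006, mm10), stood at 96.4 ± 8.31 CPM at 6 months, 75.3 ± 8.70 CPM at 15 months and 74.8 ± 3.51 CPM at 21 months (SD, n = 3 each). Its log2 fold change was -0.37 (SE 0.11, adjusted p = 0.254, edgeR) at 21 against 6 months and -0.36 (SE 0.11, adjusted p = 0.342) at 15 against 6 months. These differences did not pass the threshold, although all 3 older mice lay below all 3 younger ones in each. A two-sided exact permutation test gave p = 0.1 in both, the smallest that 3 against 3 mice allow. Between 21 and 15 months the log2 fold change was -0.01 (SE 0.11), with an exact permutation p of 0.9. The last exon of Thra, exon 10, shares 263 bases (98768157 to 98768419) with an exon of Nr1d1 on the opposite strand. Whether reads were counted by strand is not given in the sources used here, so reads of this stretch cannot be assigned to either gene.

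Thrb, which encodes the other nuclear thyroid hormone receptor (Entrez ID 21834, chromosome 14, 17659225 to 18040097), stood at 34.2 ± 1.09, 29.97 ± 1.93 and 31.5 ± 2.39 CPM at 6, 15 and 21 months (SD, n = 3 each). Its log2 fold changes were -0.12 (SE 0.09, adjusted p = 0.699) at 21 against 6 months, -0.19 (SE 0.09, adjusted p = 0.522) at 15 against 6 months and 0.07 (SE 0.09) at 21 against 15 months. The exact permutation p was 0.3, 0.1 and 0.4 in the same order, and none of the 3 differences passed the threshold.

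**Figure D2:**
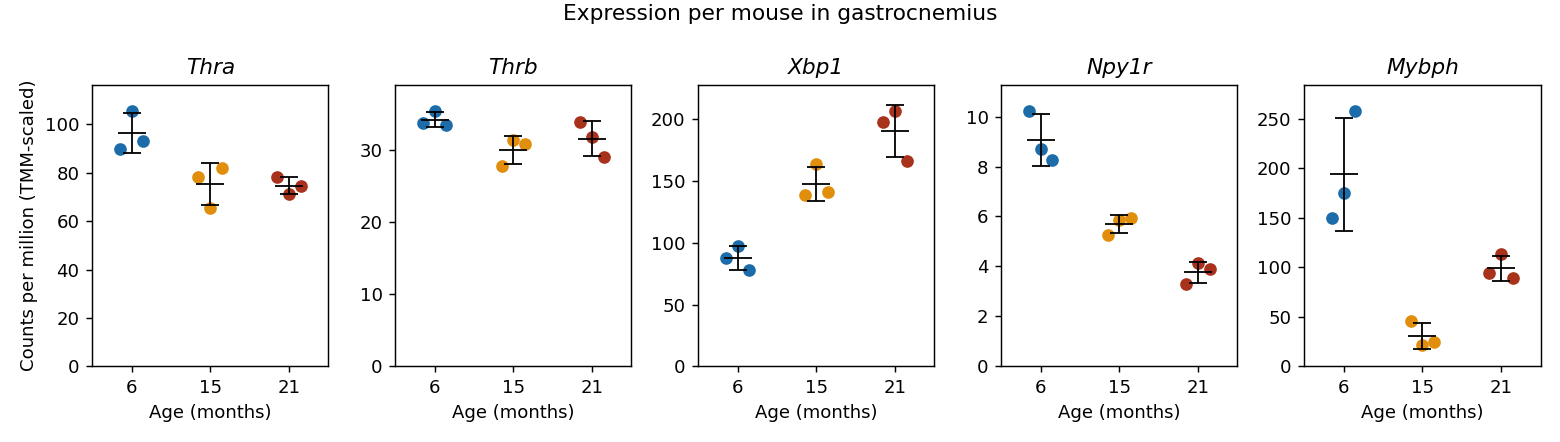
CPM of Thra, Thrb, Xbp1, Npy1r and Mybph against age in months. Each coloured point is 1 mouse, and the black bars are the mean and SD of 3 mice. Xbp1 averaged 87.6 CPM at 6 months and 190 CPM at 21 months, while Npy1r averaged 9.07 and 3.77 CPM.

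At 21 against 6 months, 2 genes passed adjusted p < 0.05 in edgeR. Xbp1, a transcription factor of the unfolded protein response (Entrez ID 22433, chromosome 11, 5520641 to 5525993), rose from 87.6 ± 9.58 to 190 ± 21.3 CPM (SD, n = 3 each), a log2 fold change of 1.12 (SE 0.12, adjusted p = 0.0423). Npy1r, a receptor for neuropeptide Y (Entrez ID 18166, chromosome 8, 66697149 to 66706800), fell from 9.07 ± 1.04 to 3.77 ± 0.419 CPM, a log2 fold change of -1.26 (SE 0.15, adjusted p = 0.0423). In both genes all 3 older mice lay outside the range of the younger ones. For 3 against 3 mice chance gives this in 10% of genes not picked by their p-value. Both genes were called on the same values, so it is no separate support. The next smallest p-values belonged to Gadd45g, a growth arrest and stress gene, at -1.52 (SE 0.20), Irx3, a homeobox factor, at 1.12 (SE 0.16), and Pnpla3, a lipid droplet protein, at -2.70 (SE 0.38). Those 3 had an adjusted p of 0.0585 in edgeR and did not pass there, while DESeq2 called all 3, with adjusted p of 4.10e-09, 5.83e-05 and 6.96e-10 in that order, and so did edgeR without mouse 3 at 6 months (0.0454, 0.0430 and 0.0107).

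At 21 against 6 months 1388 genes had an unadjusted p under 0.05, 671 higher and 717 lower. Unchanged genes would give 652.2 on average. Many genes vary together within a library, so a count can lie far from that average without an effect of age. DESeq2 called 196 genes, both of edgeR's among them. The count fell to 0 without mouse 1 or 2 of either age, and was 42 without mouse 3 at 6 months and 4 without mouse 3 at 21 months. Without mouse 1 or 3 of the 15-month group, which enters through the shared spread, it was 5 and 7. It was 3 without the 3 outlying libraries, with Xbp1 among them and Npy1r not. Npy1r also did not pass with total count scaling or the replicate block, and neither gene was among the 3 called with only the 2 groups compared.

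Of 29 lists fixed before the data were examined, 9 were called at 21 against 6 months by camera with a preset correlation, 3 higher and 6 lower. Each of these 9 lost its call with an estimated correlation, where adjusted p = 0.783 with an estimated correlation for each of them. Across the 29 lists fry called 0 in a common direction, its smallest adjusted p being 0.291. Its mixed test, which asks for change in either direction, passed for 5 lists: senescence (adjusted p = 0.000110), glycolysis and heat shock (0.00343 each), denervation (0.00387) and immediate early genes (0.0118). Without the 3 outlying libraries 3 of the 9 camera calls held, those of glycolysis (median -0.22, adjusted p = 0.000664), antigen presentation (median -0.56, adjusted p = 0.00807) and macrophage markers. The calls of slow fibre, fast fibre, heat shock, immediate early, excitation-contraction and thyroid receptor genes were lost there, with adjusted p of 0.706, 0.438, 0.0755, 0.438, 0.293 and 0.179. List members are named below as the pair with the highest mean level in a called list, or, chosen after their values were seen, as members past the threshold adjusted over the list alone. Over all 13044 genes edgeR called 0 of those members in any of the 3 comparisons of ages, while DESeq2 called 16 of 39 at 21 against 6 months, 8 of 48 at 15 against 6 months and 1 of 16 at 21 against 15 months. Of 23 member calls adjusted over a list alone at 21 against 6 months, 10 held in each of the 9 fits without 1 library: Hspa5, Hsp90aa1, Bag3, Myc, Runx1, Sln, Mmp3, Igfbp3, Lmnb1 and Cry1.

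Slow fibre genes had a median log2 fold change of 1.66, with 12 of 12 members higher and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.000191). Atp2a2, the slow calcium pump, stood at 1.02 (SE 0.37) and Myoz2, a protein of the slow fibre Z-disc, at 1.35 (SE 0.98). The call was lost without mouse 3 at 21 months, where the median was 0.71, and held without mouse 1 at 6 months, where it was 2.60. The median was 0.38 without the 3 outlying libraries (adjusted p = 0.706). Fast fibre genes had a median of -0.20 and a mean of -0.03, with 11 of 13 lower (adjusted p = 0.0436). Atp2a1, the fast calcium pump, stood at -0.32 (SE 0.20) and Myh4 at -0.03 (SE 0.26), and Myh4 was above 0 with total count scaling, at 0.05. The fast fibre call was lost without mouse 2 or 3 at 6 months, mouse 2 at 15 months or mouse 3 at 21 months, with medians of -0.10, -0.25, -0.20 and -0.16 and adjusted p of 0.135, 0.0862, 0.0596 and 0.266. It was lost too with no filter (adjusted p = 0.0540) and held with total count scaling, where the median was -0.11.

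Glycolysis and glycogen genes had a median of -0.32, with 15 of 16 members lower (camera adjusted p = 1.03e-05), and 4 members passed adjusted over the list alone. Pgk1, Eno3 and Ldha, enzymes of the lower pathway, stood at -0.45 (SE 0.14), -0.45 (SE 0.14) and -0.45 (SE 0.12), and Hk2, which phosphorylates glucose, stood the other way at 0.57 (SE 0.15). The abundant Aldoa and Gapdh stood at -0.37 (SE 0.17) and -0.37 (SE 0.14). This call held in each of the 9 fits that left out 1 library. Excitation-contraction and calcium genes had a median of -0.18, with 11 of 13 lower (adjusted p = 0.0284). Their most abundant members were Atp2a1, with the value given above, and Ryr1, the calcium release channel, at -0.18 (SE 0.18). The call was lost without mouse 2 or 3 at 6 months or mouse 3 at 21 months, with medians of -0.15, -0.10 and -0.13 and adjusted p of 0.0582, 0.107 and 0.150. It held without mouse 2 at 21 months (median -0.27) and with total count scaling (median -0.10).

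Antigen presentation genes had a median of -0.58, with 11 of 11 members lower (camera adjusted p = 0.000191). The call held in each of the 9 fits without 1 library, but without mouse 1 at 6 months the median was -0.19 (adjusted p = 0.0362). B2m, the light chain of class I molecules, stood at -0.41 (SE 0.20), H2-D1 at -0.49 (SE 0.21) and Tap1, the peptide transporter and the single member past the threshold adjusted over the list alone, at -1.15 (SE 0.28), a pass lost without mouse 1 at 6 months or mouse 1 or 3 at 21 months. Macrophage markers had a median of -0.35, with 10 of 10 lower (adjusted p = 0.0284), Lyz2 at -0.42 (SE 0.31) and Mrc1 at -0.33 (SE 0.24). Mouse 1 at 6 months had the highest level of the class II chain Cd74, 114 CPM against 42.2 and 44.1 CPM in its group. Without that mouse the macrophage median was -0.06 and its call was lost (adjusted p = 0.309), as it was without mouse 2 at 21 months (median -0.15, adjusted p = 0.268). The macrophage median was larger without mouse 3 at 21 months, at -0.62, and without the 3 outlying libraries, at -0.83 (adjusted p = 0.000162).

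Heat shock and chaperone genes had a median of 0.60, with 9 of 10 members higher (camera adjusted p = 0.00159). Adjusted over the list alone, 3 members passed: Hspa5, the main chaperone of the endoplasmic reticulum, at 1.39 (SE 0.21), Hsp90aa1 at 0.70 (SE 0.15) and Bag3, a co-chaperone, at 0.51 (SE 0.13). Hspa8 stood at 0.08 (SE 0.16) and Cryab at 0.49 (SE 0.49). Immediate early genes had a median of 0.64, with 7 of 9 higher (adjusted p = 0.0288). Junb, Egr1 and Myc, at 0.91 (SE 0.27), 1.65 (SE 0.57) and 0.82 (SE 0.15), passed adjusted over the list alone, while Jun stood at 0.02 (SE 0.21) and Nr4a1 at -0.32 (SE 0.22). Without mouse 3 at 6 months the calls were lost, with medians of 0.60 and 0.25, and without mouse 3 at 21 months also, with medians of 0.22 and 0.37. The immediate early call was lost too without mouse 1 at 15 months, with no filter and with total count scaling (adjusted p of 0.0512, 0.0633 and 0.0849, medians of 0.64, 0.41 and 0.72). Without mouse 1 at 21 months Junb stood at 0.60, without mouse 3 at 21 months Egr1 stood at 0.66, and neither then passed over the list alone.

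The list of thyroid hormone receptors, deiodinases, transporters and cofactors had a median of -0.20, with 14 of 16 members lower (camera adjusted p = 0.0288) and 0 past the threshold adjusted over the list alone. Rxra, a partner of the receptors, stood at -0.21 (SE 0.14) and Slc16a10, a hormone transporter, at -0.44 (SE 0.20). The call was lost without mouse 3 at 6 months (median -0.15, adjusted p = 0.157) or mouse 3 at 21 months (median -0.14, adjusted p = 0.169), and held with total count scaling, where the median was -0.11. Thyroid hormone-responsive genes were not called (median -0.20, adjusted p = 0.456), and Hk2 was the single member of 14 past the threshold adjusted over the list alone.

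Lists that were not called at 21 against 6 months, 20 of the 29, had adjusted p from 0.0709 to 0.993. Denervation and neuromuscular junction genes had a median of 0.07, and 3 members passed adjusted over the list alone. These were Runx1, a factor induced in denervated muscle, at 1.44 (SE 0.22), Sln, a small inhibitor of the calcium pump, at 1.998 (SE 0.37), and Ache, the acetylcholinesterase, at -0.50 (SE 0.13). Among antioxidant genes, with a median of 0.07, the metallothioneins Mt1 and Mt2 passed adjusted over the list alone at 2.08 (SE 0.56) and 3.25 (SE 0.79). Mouse 1 at 21 months held 171 CPM of Mt2 against 26.8 and 23.6 CPM in its group, and without that mouse Mt1 and Mt2 stood at 0.96 and 1.70. Among senescence genes, with a median of 0.42, 3 members passed adjusted over the list alone: Mmp3 at 2.59 (SE 0.51), Igfbp3 at -1.22 (SE 0.28) and Lmnb1 at -0.53 (SE 0.13). Ddit4, an mTOR inhibitor, stood at -2.49 (SE 0.54) among insulin, IGF and mTOR genes, with a median of 0.004 and a mean of -0.19. Usp18 stood at -0.86 (SE 0.23) among interferon-stimulated genes, with a median of -0.34, and Cry1 at -0.70 (SE 0.13) among circadian clock genes, with a median of 0.17. Those 3 were each the single member of their list past the threshold adjusted over the list alone.

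Median log2 fold changes of the remaining gene groups, none called and with 0 members past the threshold adjusted over the list alone, were 0.29 for fatty acid oxidation, -0.18 for atrophy and FoxO, -0.14 for myogenic regulators, -0.19 for collagen and extracellular matrix and 0.05 for autophagy. Nuclear oxidative phosphorylation genes had a median of 0.03 while the direction of their test was lower. Medians of cell type markers were -0.08 for satellite cells, -0.15 for fibro-adipogenic progenitors, 0.06 for tenocytes, 0.16 for smooth muscle and pericytes, -0.03 for Schwann cells and -0.19 for erythrocytes. Endothelial markers had a median of -0.02 and a mean of 0.04, and the direction of their test was higher. Another 6 lists had fewer than 5 measured members and were not tested: mitochondrially encoded genes and T and NK cell markers with 0, B and plasma cell markers with 1, neutrophil markers with 3, and adipocyte markers and sex-linked genes with 4 each.

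**Figure D3:**
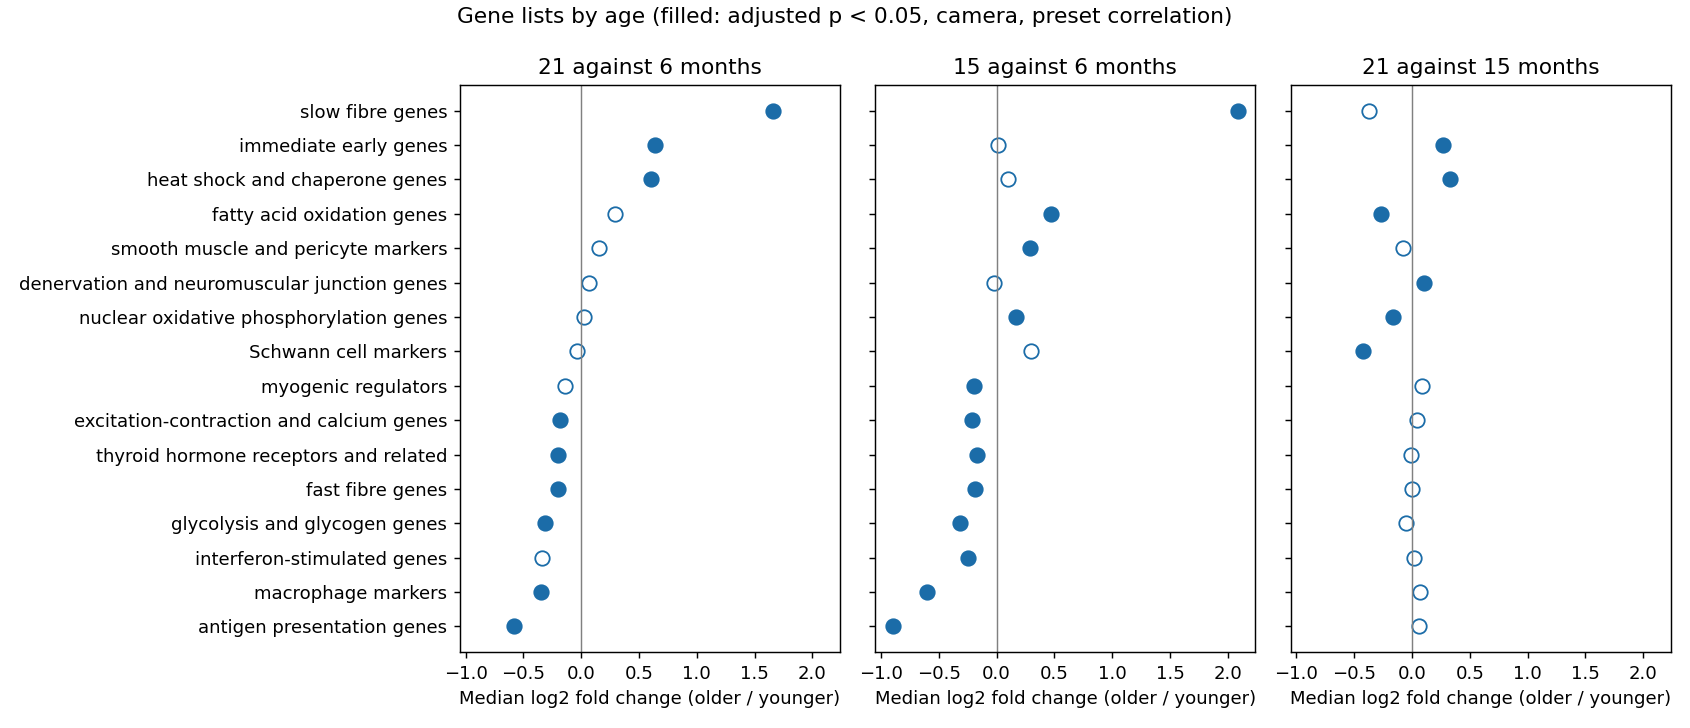
Median log2 fold change, older over younger, of each list called in at least 1 comparison, with a panel per comparison. Filled points passed adjusted p < 0.05 in camera with a preset correlation, and open points did not. Slow fibre genes lie farthest from 0, at 1.66 for 21 against 6 months and 2.09 for 15 against 6 months.

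At 15 against 6 months, 1 gene passed in edgeR. Mybph, a myosin-binding protein of the thick filament (Entrez ID 53311, chromosome 1, 134193418 to 134201237), fell from 194 ± 57.1 to 30.8 ± 13.2 CPM (SD, n = 3 each), a log2 fold change of -2.66 (SE 0.29) with an adjusted p of 0.0441 in edgeR. All 3 mice at 15 months lay below all 3 at 6 months. Counting either order, chance gives this in 10% of genes not picked by their p-value. Mybph was called on the same values, so it is no separate support. The next smallest p-values belonged to Irx3 at 1.09 (SE 0.16), Ogdhl, an oxoglutarate dehydrogenase-like enzyme, at 1.75 (SE 0.25), Tmem37, a membrane protein, at 1.20 (SE 0.18), and Map7, a microtubule-associated protein, at 0.81 (SE 0.13). Their adjusted p-values in edgeR were 0.136, 0.136, 0.136 and 0.174, so none passed there, while DESeq2 called all 4, with adjusted p of 0.000313, 2.51e-05, 5.65e-06 and 0.00295. Without mouse 3 at 6 months edgeR called Ogdhl (adjusted p = 0.0298) and not the other 3 (0.0576 each). At an unadjusted p under 0.05 there were 1342 genes, 640 higher and 702 lower, and DESeq2 called 110. The edgeR count fell to 0 without any single library except mouse 3 at 6 months, where it was 10, and mouse 1 at 15 months, where it stayed at 1.

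By camera with a preset correlation 12 of the 29 lists were called at 15 against 6 months, 4 higher and 8 lower. Each of the 12 lost its call, with adjusted p = 0.739 with an estimated correlation for nuclear oxidative phosphorylation genes and 0.710 for the other 11, and fry called 0 lists in a common direction (smallest adjusted p 0.348). Its mixed test passed for 3 lists, senescence and glycolysis genes (adjusted p = 0.00323 each) and thyroid hormone-responsive genes (0.00769). Without the 3 outlying libraries 3 of the 12 camera calls held, those of slow fibre, antigen presentation and macrophage genes, and the other 9 had adjusted p from 0.192 to 0.925. Of 30 member calls adjusted over a list alone, 5 held in each fit without 1 library: Hk2 in 2 lists, Cry1, Nr1d1 and Hspa5. Slow fibre genes had a median of 2.09, with 12 of 12 higher (camera adjusted p = 6.54e-07), and the call held in each fit without 1 library. Adjusted over the list alone, 6 members passed: Myh7 at 3.94 (SE 1.35), Tnni1 at 3.34 (SE 1.12), Tnnc1 at 3.26 (SE 1.15), Tnnt1 at 3.13 (SE 0.96), Myl3 at 2.68 (SE 0.93) and Atp2a2 at 1.32 (SE 0.37). Myoz2 stood at 1.70 (SE 0.99). Without the 3 outlying libraries the median was 0.99 (adjusted p = 0.000251), and these 6 members stood at 2.26, 1.79, 1.93, 1.88, 1.74 and 0.82, all but Tnnc1 still past the threshold over the list alone. Fatty acid oxidation genes had a median of 0.47 with 15 of 16 higher (adjusted p = 0.00114), Cd36, a fatty acid transporter, at 0.45 (SE 0.35) and Pdk4, a kinase that slows glucose oxidation, at -0.69 (SE 0.97). Nuclear oxidative phosphorylation genes had a median of 0.16 with 28 of 30 higher (adjusted p = 0.00135), Atp5b at 0.14 (SE 0.19) and Atp5a1 at 0.22 (SE 0.21). Both oxidative lists lost their call without mouse 1 at 15 months, with medians of 0.13 and 0.06, and without mouse 3 at 6 months, with medians of 0.34 and 0.16. Their medians were larger without mouse 3 at 15 months, at 0.71 and 0.28, and that of oxidative phosphorylation genes also without mouse 1 at 6 months and with total count scaling, at 0.26 and 0.25.

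Smooth muscle and pericyte markers had a median of 0.29 with 7 of 7 higher (camera adjusted p = 0.0335), Rgs5 at 0.29 (SE 0.16) and Pdgfrb at 0.01 (SE 0.11). Fast fibre genes had a median of -0.19 but a mean of 0.006, with 11 of 13 lower (adjusted p = 0.0173), Atp2a1 at -0.38 (SE 0.20) and Myh4 at -0.09 (SE 0.26). Excitation-contraction and calcium genes had a median of -0.21 with 11 of 13 lower (adjusted p = 0.00485), and Ryr1 stood at -0.21 (SE 0.18). Each of these calls was lost without mouse 1 at 15 months, with medians of 0.18, -0.11 and -0.15 and adjusted p of 0.259, 0.362 and 0.249. Without mouse 2 at 6 months the first and the second were lost too (medians of 0.15 and -0.11, adjusted p of 0.575 and 0.103). The first was also lost without mouse 2 at 15 months (median 0.32, adjusted p = 0.0604) and with total count scaling (median 0.36, adjusted p = 0.0814). The second held without mouse 3 at 15 months, at -0.30, and with total count scaling, at -0.11. Glycolysis and glycogen genes had a median of -0.31 with 13 of 16 lower (adjusted p = 0.000178), Aldoa at -0.32 (SE 0.17) and Gapdh at -0.27 (SE 0.14). Pgk1 at -0.49 (SE 0.14) and Hk2 at 0.79 (SE 0.15) passed adjusted over the list alone. The glycolysis call held in each fit without 1 library and was lost without the 3 outlying libraries (median -0.13, adjusted p = 0.192).

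Antigen presentation genes had a median of -0.90 with 11 of 11 lower (camera adjusted p = 1.39e-05). The call held in each fit without 1 library, but without mouse 1 at 6 months the median was -0.27 (adjusted p = 0.00234). Adjusted over the list alone, 6 members passed: Ciita, the master regulator of class II genes, at -1.20 (SE 0.34), H2-Ab1 at -1.07 (SE 0.31), H2-Aa at -1.05 (SE 0.30), Tap1 at -0.97 (SE 0.28), H2-Eb1 at -0.95 (SE 0.36) and Cd74 at -0.90 (SE 0.34). Without mouse 1 at 6 months Ciita, H2-Ab1, H2-Aa, H2-Eb1 and Cd74 stood at -0.79, -0.50, -0.56, -0.27 and -0.27, and none of the 6 passed over the list alone. B2m stood at -0.40 (SE 0.20) and H2-D1 at -0.46 (SE 0.21). Macrophage markers had a median of -0.60 with 10 of 10 lower (adjusted p = 0.00114), Lyz2 at -0.72 (SE 0.32) and Mrc1 at -0.41 (SE 0.24), a call lost without mouse 3 at 15 months (median -0.40, adjusted p = 0.0678). It held without mouse 1 at 6 months (median -0.36, adjusted p = 0.0472) and without mouse 1 at 15 months (median -0.91). Without the 3 outlying libraries the macrophage median was -1.04 (adjusted p = 4.28e-07) and that of antigen presentation genes -0.92 (adjusted p = 0.00329). Mouse 1 at 6 months was again the library with the most Cd74, at 114 CPM. Interferon-stimulated genes had a median of -0.25 with 11 of 13 lower (adjusted p = 0.0335), with Ifit2 at 0.09 (SE 0.12). That call was lost without mouse 1 or 2 at 6 months, mouse 1 at 15 months or mouse 3 at 21 months, with medians of -0.08, -0.17, -0.28 and -0.25 and adjusted p of 0.338, 0.200, 0.205 and 0.0533, and it held without mouse 3 at 6 months (median -0.41).

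The list of thyroid hormone receptors, deiodinases, transporters and cofactors had a median of -0.17 with 15 of 16 lower (camera adjusted p = 0.0151). Dio2, the deiodinase that makes the active hormone, stood the other way at 1.25 (SE 0.31) and was the single member past the threshold adjusted over the list alone. Rxra stood at -0.20 (SE 0.14) and Slc16a10 at -0.44 (SE 0.20), and the call was lost without mouse 3 at 6 months (median -0.12, adjusted p = 0.0956) or mouse 1 at 15 months (median -0.12, adjusted p = 0.266). With total count scaling it held, at a median of -0.09. Myogenic regulators had a median of -0.20 with 8 of 10 lower (adjusted p = 0.0335), Mef2c at -0.10 (SE 0.13) and Mef2a at -0.15 (SE 0.13). Myog, a differentiation factor that the denervation list also holds, passed adjusted over each of these lists alone at -0.97 (SE 0.23). The myogenic call was lost without mouse 2 at 6 months, mouse 1 at 15 months or mouse 2 at 15 months, with medians of -0.11, -0.12 and -0.15 and adjusted p of 0.228, 0.0896 and 0.0692. It was lost too with no filter (adjusted p = 0.0681) and held with total count scaling, where the median was -0.12. Among thyroid hormone-responsive genes, which were not called (adjusted p = 0.508), Atp2a2, Hk2 and Bcl3 passed adjusted over the list alone, Bcl3 at -1.02 (SE 0.32).

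Lists that were not called at 15 against 6 months, 17 of the 29, had adjusted p from 0.0614 to 0.952. Circadian clock genes had a median of 0.26, and 6 of their 16 members passed adjusted over the list alone, in both directions. Arntl, Npas2, Cry1 and Nr1d1 stood lower at -1.28 (SE 0.35), -1.99 (SE 0.65), -0.64 (SE 0.13) and -0.86 (SE 0.16), and Per2 and Per3 stood higher at 1.33 (SE 0.43) and 1.02 (SE 0.33). Hspa5 at 1.05 (SE 0.21) and Bag3 at 0.47 (SE 0.13) passed adjusted over the heat shock list alone (median 0.10), Ddit4 at -2.12 (SE 0.53) over the insulin, IGF and mTOR list alone (median -0.06), and Myc at 0.55 (SE 0.16) over the immediate early list alone (median 0.02). Without mouse 1 at 15 months Npas2 stood at -3.50 and Bag3 at 0.31, and Bag3 then did not pass. Median and mean differed in sign for denervation genes (-0.02 and 0.05), senescence genes (-0.23 and 0.08), autophagy genes (0.01 and -0.007) and fibro-adipogenic progenitor markers (0.01 and -0.09).

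At 21 against 15 months edgeR called 0 genes, and the smallest adjusted p was 0.653. There were 237 genes at an unadjusted p under 0.05, fewer than the average of 652.2 for unchanged genes, and DESeq2 called 3. The smallest p-values belonged to Mybph at 1.69 (SE 0.29), Xlr3b, an X-linked gene, at -3.92 (SE 0.67), Runx1 at 1.29 (SE 0.22), Lrat, the retinol acyltransferase, at 1.33 (SE 0.31), and Fam174b at 1.19 (SE 0.28). Mybph averaged 30.8 ± 13.2 CPM at 15 months, and Xlr3b averaged 0.346 ± 0.302 CPM at 21 months and 5.29 ± 1.56 CPM at 15 months (SD, n = 3 each). None of the 5 passed in edgeR, and the 3 DESeq2 calls were Mybph, Xlr3b and Runx1, with adjusted p of 3.47e-06, 4.36e-07 and 0.00708. Xlr3b belongs to a family of near-identical X-linked copies, so its value is uncertain where reads were split between copies.

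By camera with a preset correlation 6 lists were called at 21 against 15 months, 3 higher and 3 lower. Each lost its call: adjusted p = 0.972 with an estimated correlation for the 3 lower lists and 0.565 for the 3 higher ones, and fry called 0 in a common direction (smallest adjusted p 0.794) and 0 in its mixed test (smallest adjusted p 0.212). Nuclear oxidative phosphorylation genes had a median of -0.16 with 30 of 30 lower (camera adjusted p = 3.71e-06), Atp5b at -0.13 (SE 0.19) and Atp5a1 at -0.15 (SE 0.21). Fatty acid oxidation genes had a median of -0.27 with 16 of 16 lower (adjusted p = 0.0351), Pdk4 at -0.43 (SE 0.97) and Cd36 at -0.13 (SE 0.34). Schwann cell markers had a median of -0.42 with 7 of 7 lower (adjusted p = 0.0105), Pmp22 at -0.33 (SE 0.20) and Mbp at -0.45 (SE 0.22), both myelin proteins. Without mouse 1 at 15 months, the library with the most Myh7, these 3 calls were lost and the medians were -0.04, 0.13 and -0.05. Without all 3 outlying libraries, that mouse among them, the medians were -0.24, -0.22 and -0.11, and the first call held (adjusted p = 2.34e-08) while the others did not (0.0613 and 0.382). The first was also lost without mouse 2 at 21 months (median -0.05) and the third without mouse 3 at 21 months (median -0.43, adjusted p = 0.0976). The first held without mouse 3 at 15 months, at -0.26, and without mouse 1 or 3 at 21 months, at -0.09 and -0.36. The second was also lost without mouse 2 or 3 at 6 months or mouse 1 or 2 at 21 months, with medians of -0.27, -0.27, -0.16 and -0.10 and adjusted p of 0.0635, 0.0820, 0.359 and 0.785. Without mouse 3 at 15 or at 21 months it held, at -0.46 and -0.56.

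Heat shock and chaperone genes had a median of 0.33 with 10 of 10 higher at 21 against 15 months (camera adjusted p = 0.000290), Hspa8 at 0.29 (SE 0.16) and Cryab at 0.21 (SE 0.49). Immediate early genes had a median of 0.27 with 7 of 9 higher (adjusted p = 0.0105), Nr4a1 at -0.22 (SE 0.22) and Jun at 0.004 (SE 0.21). Without mouse 3 at 21 months both calls were lost, with medians of 0.15 and -0.05. Without all 3 outlying libraries, that mouse among them, the heat shock call held (median 0.37, adjusted p = 0.00305) and the immediate early call did not (median 0.25, adjusted p = 0.529). The first was also lost without mouse 3 at 15 months (median 0.19), and the second without mouse 1 or 2 at 15 months (medians 0.20 and 0.20), while its median was 0.41 without mouse 3 at 15 months. Denervation and neuromuscular junction genes had a median of 0.10 with 11 of 20 higher (adjusted p = 0.0105), Musk at 0.47 (SE 0.34) and Chrnb1 at 0.27 (SE 0.12). Runx1, and Sln at 1.33 (SE 0.35), passed adjusted over the list alone. That call was lost without mouse 2 at 21 months, where the median was 0.04. It held without mouse 1 or 2 at 15 months or mouse 1 at 21 months, with medians of 0.24, 0.01 and 0.18, and without the 3 outlying libraries (median 0.13, adjusted p = 0.00142). Mt1 and Mt2, at 1.86 (SE 0.55) and 3.08 (SE 0.79), passed adjusted over the antioxidant list alone, although the list was not called (adjusted p = 0.623). Without mouse 1 at 21 months they stood at 0.74 and 1.53 and did not pass. The other 22 lists were not called either, with adjusted p from 0.0749 to 0.973. Median, mean or direction of the test differed in sign for the thyroid receptor list (-0.008, -0.06, higher), fast fibre (0.004, -0.04, higher), clock (-0.05, -0.03, higher) and interferon-stimulated genes (0.02, -0.01, higher).

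Across the 3 ages together, an F-test with edgeR called 0 genes, and the smallest adjusted p was 0.0835. There were 1115 genes at an unadjusted p under 0.05, and a DESeq2 likelihood ratio test called 200. The contrast of 15 months with the mean of 6 and 21 months also called 0 genes in edgeR. It gave 491 genes at an unadjusted p under 0.05, a smallest adjusted p of 0.120, and 7 genes in DESeq2. Without mouse 3 at 6 months the F-test called 10 genes, without mouse 1 at 15 months 2 and without mouse 3 at 21 months 1. The other contrast called 1 gene without mouse 1 at 15 months.

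The changes at 21 and at 15 months, both measured against the same 6-month mice, shared 0 genes past the adjusted threshold in edgeR. DESeq2 shared 69, 27 higher and 42 lower in both, and edgeR without mouse 3 at 6 months shared 9, 1 higher and 8 lower. At an unadjusted p under 0.05 they shared 735 genes, 357 higher and 378 lower in both, and 0 genes stood in opposite directions. In 20 simulations of unchanged groups against shared controls, with each gene drawn independently, the mean was 134 shared genes. Independent lists of these sizes would share 32.9 higher and 38.6 lower. Across genes, which are not independent replicates, the fold changes correlated at 0.799 against a simulated mean of 0.497. The covariance was 0.102 against 0.0327 in simulation. The 3 control mice could not be divided into parts of at least 2 each, so part of the excess may come from the shared controls. The simulations also lacked variation that many genes share within a library, such as the first principal component with 35.2% of the variance. They therefore cannot show how much overlap and correlation the shared controls alone would give.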

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

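Total count scaling, leaving out the 3 outlying libraries and the contrast of both older ages with 6 months were chosen after seeing the data, and the other alternatives were planned. Of 2968 values of single genes under an alternative, 2603 kept their direction and side of the threshold, 239 were no longer past it, 84 were newly past it and 42 reversed. Most of these values belong to genes that did not pass in the main fit, so the 2603 do not show that calls are stable. Only values of genes past the threshold there could be among the 239. Of 432 values of called lists, with the direction that camera's test gives, 302 kept both, 129 were no longer past the threshold and 1 reversed. With 3 mice per age and 15354396 to 17317856 counts per library, changes under 2-fold were often missed on simulated data. A missing call therefore says little about small changes. Simulated genes varied independently, so the shares recovered need not hold for the real libraries. Some large fold changes also did not pass in edgeR at 21 against 6 months. Pnpla3 stood at -2.70 (adjusted p = 0.0585, edgeR) and Ddit4 at -2.49 (adjusted p = 0.135, edgeR). The cause was not tested for any of the values that follow, except that fry by construction tests another hypothesis than camera. The pseudocount alternative applied to normalized values only and was not run on counts.

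For 21 against 6 months edgeR called 2 genes, and the count was 30 with no filter, 196 with DESeq2 (94 higher, 102 lower), 59 with sample quality weights (22 higher, 37 lower), 1 with total count scaling, 3 without the 3 outlying libraries (1 of the 2 among them) and 0 to 42 leaving out 1 library. For 15 against 6 months it called 1 gene, and the count was 0 with the strict filter, 0 with only the 2 groups compared, 0 with total count scaling, 110 with DESeq2 (38 higher, 72 lower) and 0 to 10 leaving out 1 library. For 21 against 15 months it called 0, and the count was 3 with DESeq2, 1 with sample quality weights and 0 leaving out any library. The F-test called 0, against 5 with no filter, 200 with DESeq2, 3 with sample quality weights and 0 to 10 leaving out 1 library. The contrast of 15 months with the mean of 6 and 21 months called 0, against 1 with no filter, 7 with DESeq2, 1 with sample quality weights and 0 to 1 leaving out 1 library. The mean of 15 and 21 months against 6 months gave 36 calls, against 60 with no filter, 314 with DESeq2 (all 36 among them), 73 with sample quality weights (33 of the 36 among them), 1 with total count scaling, 2 without the 3 outlying libraries and 0 to 74 leaving out 1 library. The overlap of both comparisons with 6 months was 0 genes, against 735 at the unadjusted threshold, 69 with DESeq2 and 0 to 9 leaving out 1 library, where 9 came without mouse 3 at 6 months. It was 0 too with RLE scaling, no filter, the strict filter, the replicate block, only the 2 groups compared, sample quality weights, total count scaling and without the 3 outlying libraries.

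Same-numbered libraries of different ages did not deviate together. Over 9 such pairs the correlation of deviations ran from -0.42 to 0.41, 2 were over 0.1, and 2 of 9 libraries correlated best with their own number. With the replicate block the count was 5 at 21 against 6 months (1 of the 2 genes among them), 0 at 15 against 6 months, 5 in the F-test and 3 for the mean of 15 and 21 months against 6 months, and Pdk4 at 21 against 15 months was 0.13.

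The number of lists called was 9, 12 and 6 at 21 against 6, 15 against 6 and 21 against 15 months. It was 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry in a common direction, and 6, 5 and 6 without the 3 outlying libraries. Leaving out 1 library it ran from 5 to 12, from 5 to 15 and from 4 to 9. The fatty acid oxidation median at 21 against 15 months, -0.27, was 0.13 without mouse 1 at 15 months. The immediate early median in that comparison, 0.27, was -0.05 without mouse 3 at 21 months.

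Single genes that reversed had small or unsteady values. With sample quality weights Thra at 21 against 15 months was 0.065, Pdk4 0.76 and Cd36 0.035, and at 21 against 6 months Myh4 was 0.068, Cryab -0.076 and Jun -0.029. With total count scaling Myh4 at 21 against 6 months was 0.053. Without the 3 outlying libraries Thra at 21 against 15 months was 0.022, Pdk4 0.71, Cd36 0.18 and Jun -0.066. In the same setting Myh4 at 21 against 6 months was 0.088 and Cryab -0.36, and at 15 against 6 months Myh4 was 0.098, Atp5a1 -0.021, Mef2a 0.020 and Pdgfrb -0.082.

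Leaving out 1 library also reversed single genes. At 21 against 6 months the range over such fits was from -0.16 to 0.11 for Myh4, from -0.034 to 0.21 for Hspa8, from -0.15 to 0.87 for Cryab and from -0.18 to 0.18 for Jun. At 15 against 6 months the range over such fits was from -0.28 to 0.12 for Myh4, from -0.074 to 0.71 for Cd36 and from -0.053 to 0.076 for Pdgfrb. At 21 against 15 months the range over such fits was from -0.10 to 0.055 for Thra, from -0.91 to 1.03 for Pdk4, from -0.40 to 0.39 for Cd36, from -0.43 to 0.83 for Cryab, from -0.46 to 0.046 for Nr4a1, from -0.12 to 0.16 for Jun and from -0.56 to 0.13 for fatty acid oxidation genes.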

Other observations

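The contrast of both older ages with 6 months, the tests of slow fibre, endoplasmic reticulum and Thra patterns, and the counts of other splits were all chosen or predicted only after the results had been seen. In that contrast, of 6 older mice with 3 mice at 6 months, edgeR called 36 genes, 12 higher and 24 lower. Most of these calls were lost with total count scaling, with the replicate block or without the 3 outlying libraries, as counted above. In each of the 36 the older and younger mice did not overlap. Chance gives this in 2.38% of genes not picked by their p-value. These genes were called on the same values, so it is no separate support. Hspa5, the endoplasmic reticulum chaperone, rose from 236 ± 15.8 to 555 ± 139 CPM (SD, n = 3 at 6 months and 6 older mice), a log2 fold change of 1.22 (SE 0.19), and Xbp1 rose by 0.94 (SE 0.11). Nr4a3, an orphan nuclear receptor, rose from 2.18 ± 0.820 to 9.55 ± 2.91 CPM, a log2 fold change of 2.13 (SE 0.33), and Irx3, Ogdhl, Ccn5, Sybu, Tmem37, B3gnt2 and Map7 rose by 1.11 (SE 0.14), 1.55 (SE 0.23), 1.38 (SE 0.22), 1.24 (SE 0.20), 0.98 (SE 0.16), 0.75 (SE 0.11) and 0.71 (SE 0.11). Adjusted p in edgeR lay from 0.0327 to 0.0449 for the genes named here.

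Srebf1, a regulator of lipid synthesis, fell from 75.8 ± 19.6 to 34.8 ± 5.66 CPM, a log2 fold change of -1.12 (SE 0.17), and Pnpla3, a lipid droplet protein that it is known to regulate, fell from 19.5 ± 8.08 to 3.64 ± 1.46 CPM, a log2 fold change of -2.44 (SE 0.30). The 4 measured adipocyte markers had a mean log2 level, relative to all libraries, of 2.47 in mouse 2 at 6 months. In mice 1 and 3 of that age it was -0.64 and -0.16, and both genes still stood above all older mice there. Fat in the samples was not tested as a source of these differences. Asb2, a ubiquitin ligase component of muscle, fell from 981 ± 275 to 452 ± 73.4 CPM, a log2 fold change of -1.13 (SE 0.17). Mybph, Tgtp1, Avil, Slc10a6, Gadd45g, Npy1r and Arrdc4 stood lower at -1.82 (SE 0.23), -1.97 (SE 0.30), -1.63 (SE 0.25), -1.41 (SE 0.20), -1.23 (SE 0.16), -0.97 (SE 0.12) and -0.87 (SE 0.14), each past the threshold. Cry1, a repressor of the circadian clock and a member of that list, fell from 33.7 ± 6.66 to 21.2 ± 0.730 CPM, a log2 fold change of -0.67 (SE 0.11, adjusted p = 0.0449 in edgeR). The count of 36 was 0 without mouse 1 or 2 at 6 months, mouse 2 at 15 months, or mouse 1 or 2 at 21 months, and it was 74 without mouse 3 at 6 months, 15 without mouse 1 at 15 months, 14 without mouse 3 at 15 months and 2 without mouse 3 at 21 months. Arntl, a core clock gene, stood at 60.4, 54.8 and 34.2 CPM in the 3 mice at 6 months, 29.4, 15.6 and 16.4 CPM at 15 months and 43.3, 33.2 and 17.0 CPM at 21 months, while Per2 stood at 8.11, 11.02 and 20.5, 15.5, 41.4 and 42.5 and 15.6, 19.8 and 30.2 CPM in the same order, and the hour of collection was not used here.

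Slow fibre genes had medians above 0 at both older ages but varied within ages, and their camera calls were lost at 21 and 15 months against 6 (adjusted p = 0.783 and 0.710 with an estimated correlation), while fry called neither. Uneven sampling of slow and fast parts of the muscle may account for this: the mean slow fibre score differed by 1.91 within-age SDs at 15 against 6 months and by 1.39 at 21 against 6 months, both under the bound of 2 set for the test. Without the 3 outlying libraries the score difference was 1.12 at 15 months and 0.17 at 21 months, against 2.51 and 1.83 with them. Sampling and age cannot be told apart here, since the spread between 3 mice per age is too wide. A change of fibre type with age stays open and untested.

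A set of 13 endoplasmic reticulum genes, chosen after their values were seen, in no fixed list, with the called gene Xbp1 among them and with no set test, had a median log2 fold change of 0.46 at 15 and 0.76 at 21 months, which describes only these genes. If stromal cells kept their level of extracellular matrix genes per cell, more of them would raise that list by at least as much. The median of that list was -0.27 (SD of members 0.25) at 15 months and -0.19 (SD 0.37) at 21 months. These values argue against more stromal cells only under that assumption, which was not tested. B and plasma cells, with 1 measured marker, were not tested as a source. For these 13 genes the median without the 3 outlying libraries was 0.84 at 21 months (SE of their score difference 0.19). The slow fibre score difference there fell to 0.17. The genes were chosen after their values in these same libraries were seen. A high median in fewer of them therefore cannot decide on slow fibre content. At 15 months the median was 0.53, and a slow fibre score difference of 1.12 remained. Slow fibre content stays open at both ages. With total count scaling the medians were 0.53 and 0.84 at 15 and 21 months. That scaling moved genes by a median of 0.08 in both. So small a shift could not have removed the medians. The choice between TMM and total counts therefore does not explain them, and other errors of scaling were not tested. A response of the unfolded protein pathway in older muscle may be involved, a hypothesis that needs other mice, since genes chosen for a difference cannot show that the group moves. Handling at collection was not tested, and age itself stays an open explanation.

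Thra was lower in all older mice but did not pass its test. Without the 3 outlying libraries the log2 fold change of Thra was -0.29 (SE 0.13) at 21 months, where the slow fibre score difference fell from 1.83 to 0.17. This argues only weakly against slow fibre content as the whole cause at 21 months, since few mice were left and the value lay little over 2 SE from 0. At 15 months the log2 fold change was -0.31 (SE 0.13), but a score difference of 1.12 remained, so slow fibre content stays open there. Reads of the antisense gene Nr1d1 could contribute: scaled from 6 to 15 months, Nr1d1 predicted a change of 12.2 CPM in Thra from 15 to 21 months, the observed change was -0.54 CPM, and the difference was -12.7 CPM (SE 6.64). That lies within 2 SE, so this test cannot tell antisense reads and a lower level of Thra itself apart. The shared stretch holds 263 of 3077 exonic bases of Nr1d1 and of 4614 of Thra, which limits the reads that could be miscounted. How large their share could be was not computed. Age stays open and untested.

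For the pairwise comparisons, 3 against 3 mice make 10 splits, too few for a share under 0.05. The real split called 2 genes at 21 against 6 months and the highest other split 0, so 1 of 10 splits was as large. At 15 against 6 months 2 of 10 were as large, with 1 gene called and 2 in the highest other. At 21 against 15 months 10 of 10 were as large, with 0 called and 0 in the highest other, which a count of 0 makes certain. For lists, 5 of 10 splits were as large at 21 against 6 months (9 called, highest other 12), 4 of 10 at 15 against 6 months (12 called, highest other 16) and 6 of 10 at 21 against 15 months (6 called, highest other 14). For the F-test (highest other split 6) and for 15 months against the mean of the others (highest other split 187), the real count was 0, so that 100 of 100 splits were as large whatever the data, and the splits say nothing about chance there. For both older ages against 6 months, 3 of 100 splits gave 36 or more. Because the contrast was picked after seeing such counts, that share does not exclude chance. The highest other split gave 165 genes there. The splits with 187 and 165 genes set mice 1 and 2 at 15 months and mouse 3 at 21 months against the rest, the mice with the highest slow fibre scores, which points to a structure of the samples. A split with 122 genes, also counted among the 3, kept the 6-month mice together and divided the older mice otherwise, so it is the same contrast with another estimate of the spread.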
